A study of Mus musculus with 15 samples.

How the data were processed

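RNA was measured in 15 samples of the mouse line CH12 in 5 groups of 3, shLacZ and shMcm on day 3 and WT, C13 and C23. Libraries were prepared from ribosomal RNA-depleted total RNA with a Corall total RNA kit, per the labels' protocols. Per the submitters' processing notes, the authors used cutadapt 1.4.2, Bowtie2 2.1.0, STAR, bedtools 2.27, featureCounts 2.0.0 and DESeq2 1.22.2 with the mm9 build, and the order and settings of these steps are not given in the sources used here.

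The file analysed here is a table of the authors' own results, with no value per library. The deposited TPM values are the authors' pooled value of each gene in shLacZ and in WT, per the file headers. The deposited log2 fold changes compare shMcm with shLacZ, C13 with WT and C23 with WT, per the file headers, and by their values were moderated toward 0 at low expression. The deposited p-values are of 2 kinds, for differential expression and for being unchanged, per the file headers, printed with 4 decimals, so that a p of 0.0000 is a rounded value. Ties and blanks among the deposited p-values for differential expression resemble those of Benjamini-Hochberg adjusted values, which the file does not state, and they were used as given. The p for being unchanged lay under 0.05 for 9267, 8396 and 8741 genes in shMcm, C13 and C23, at absolute log2 fold changes of up to 0.84, 0.88 and 0.87, and 2551, 2668 and 3036 of these genes also passed the test for differential expression.

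The tests fixed before the data were examined assumed counts per library and were replaced by the authors' p-values at a threshold of 0.05. Fold changes are the authors' and no pseudocount was applied to them. Depth per sample, replicate error and adjustment over a list alone cannot be derived from these values and are not given, and the precision of a single fold change is therefore known only through its p. Set tests that need single libraries were replaced by counts of members that rose, fell or did not pass, and by the percentile of a list's median among 10000 random lists of the same size, each gene drawn within 100 ranks of the member in control TPM. A list was said to stand apart below the 2.5th or above the 97.5th percentile, as a description of these values, since genes are not replicates. The 29 lists were fixed before the data were examined and matched by symbol or unique synonym, and 2 further sets are the authors'. Lists with fewer than 3 tested members were left out.

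Genes were named by a rule fixed before the data were examined. It takes genes named in advance, among them the MCM subunits, Myc, Pvt1, Ighm and Igha, the 8 largest rises and 8 largest falls, and up to 4 members of each list with the smallest p. Its expression filter in log2 CPM was replaced by a mean of at least 8 TPM over the groups compared, which applies to the largest rises, falls and differences and to genes named as changed in both clones, as does its exclusion of provisional symbols and small RNAs. Its condition on single replicates could not be applied, and ties in p were ordered by absolute fold change. Not every list member the rule allows is printed, and some of the named genes and lists are not reported here.

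Gene names and chromosomes came from the RefSeq table of GRCm38.p6, which matched 16461 of 16483 symbols. That assembly differs from mm9, so only chromosome membership and gene order were used and no coordinates are given. Chromosome medians were tested by the exact distribution of the median under permutation of chromosome labels, with Benjamini-Hochberg adjustment over 20 chromosomes. After the data were seen, consecutive windows of 15 genes of at least 5 TPM were tested in the same way, and 3 or more adjacent windows past the threshold in the same direction were called a run. Also after the data were seen, 7-base sequences were counted, in genes above 5 TPM other than Mcm6, in the coding sequence and 3' UTR of the longest protein-coding transcript of each gene in GENCODE M21, and the trend of fold change on log2(TPM + 1) was removed by lowess with a span of 0.3. Bootstrap intervals cover 95% over 2000 draws of genes, and intervals of shares of genes are exact binomial (Clopper-Pearson).

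Shared WT samples were treated by simulating unchanged groups 100 times. The standard error of a fold change was read back from its p for differential expression, taken as adjusted, and set to the median of each of 20 classes of TPM. The steps were tested on simulated data. For C23 against WT, with 12648 genes, 5 of 5 shifted windows and 1 of 671 others were called, 5.8% of unshifted lists lay outside the matched range, and a planted 7-base sequence had rank 1. Simulated genes varied independently, and the unshifted lists were random genes. These rates thus leave out lists and neighbours whose genes vary together, and are not error rates for the lists and windows of the data. Alternatives were a filter at 1 TPM, a p under 0.01, an absolute log2 fold change of at least 1, a filter at 8 TPM, lists not matched on TPM, removal of the trend, and removal of chromosomes or of genes with a sequence. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.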

Results

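RNA levels were measured in CH12, a mouse B-cell lymphoma line that switches immunoglobulin class in culture, grown with IL-4, CD40 and TGF-beta stimulation. The 15 libraries, made from ribosomal RNA-depleted total RNA, fell into 5 groups of 3 samples. The shLacZ and shMcm groups were labelled day 3 and carried a short hairpin RNA against lacZ, a bacterial gene absent from mouse cells, or against an Mcm gene. The remaining groups were the WT line and the C13 and C23 clones, and the labels do not say what was altered in the clones. The file analysed here held 16483 genes, with TPM (length-scaled transcript abundance) of the 2 control groups and the authors' fold changes and p-values, so the depth of single libraries and the spread between replicates are unknown. Values are therefore given as the authors' own, without an SD, and a change is called where the authors' p for differential expression lay under 0.05. The labels do not say whether the 3 samples of a group came from separate cultures, so these p-values measure only the spread between those samples, which may be technical.

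The knockdown comparison asked how loss of an Mcm gene changed expression, and the targeted gene was examined at the outset. Mcm6, a subunit of the MCM2-7 replicative helicase encoded on chromosome 1, fell by 2.76 on the log2 scale from 286.7 TPM in shLacZ, with a p listed as 0.0000 (4 decimals) in the authors' deposited table. Mcm5 fell by 0.19 (p = 0.0003 in the authors' deposited table), or by 0.11 once the trend of fold change on TPM was removed. The other 4 subunits did not pass, with log2 fold changes of -0.09 for Mcm2, -0.00 for Mcm3, -0.06 for Mcm4 and 0.05 for Mcm7 in the authors' deposited table; with that trend removed the values of Mcm2, Mcm3 and Mcm4 were -0.0067, 0.08 and 0.04. The column names of the file give the targeted gene as Mcm6, whereas the labels name Mcm without a number.

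**Figure D1:**
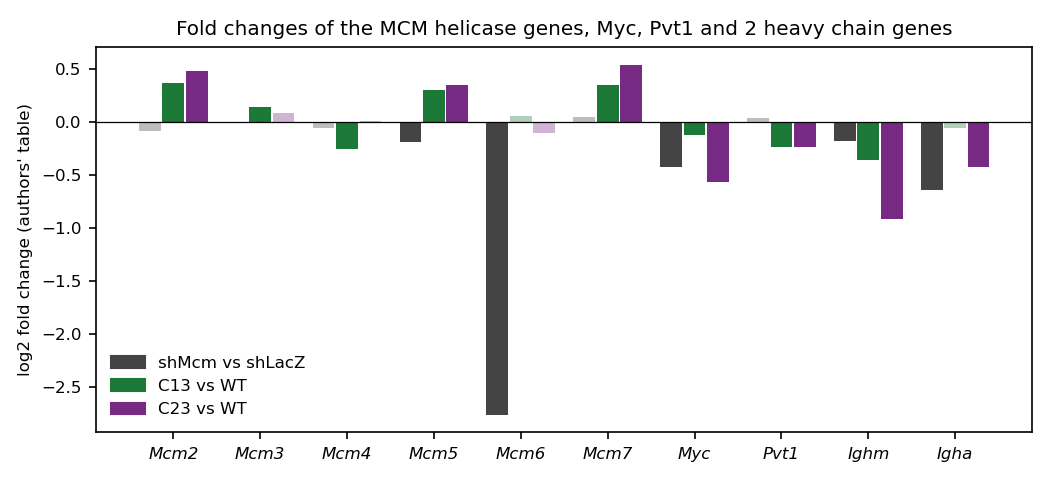
Bars give the authors' log2 fold change of each gene in shMcm against shLacZ, C13 against WT and C23 against WT, and pale bars mark genes whose p was 0.05 or above; the file gives no error for these values. Mcm6 stood at -2.76 in shMcm, and at 0.05 and -0.11 in C13 and C23, which did not pass; the C23 value was 0.0096 with the trend on TPM removed.

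Cholesterol synthesis genes fell together after the knockdown, while more NF-kB targets and genes of the replication fork rose than fell. Of 23 tested cholesterol synthesis genes 17 fell, 0 rose and 6 did not pass, with a list median of -0.39. Among the falls were those of Sc5d (-0.89), Fdps (-0.87) and Msmo1 (-0.67), all log2 fold changes from the authors' deposited table. Of 30 NF-kB targets 16 rose and 0 fell, among them Tnf (0.91), Map3k8 (0.65), Ebi3 (0.53) and Ccr7 (0.48) in the authors' deposited table. Replication fork genes counted 14 that rose and 1 that fell of 32, with log2 fold changes in the authors' deposited table of 0.64 for Dna2, a nuclease and helicase that processes flaps, 0.42 for Pole and 0.36 for Pola1, catalytic subunits of DNA polymerases epsilon and alpha. In the DNA damage and fork protection list 16 of 40 rose and 2 fell; the authors' deposited table gives 0.70 for Atm, 0.61 for Brca2 and -0.86 for Hus1.

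Among cell cycle and licensing genes more rose than fell, and most did not pass. Of 22 G1/S genes 8 rose, 2 fell and 12 did not pass, with Ccne2 (cyclin E2) at 1.27 and E2f8 at -0.87 in the authors' deposited table. Origin licensing and firing genes counted 7 that rose, 1 that fell and 19 that did not pass, led by Recql4 (0.48) and Mcm8 (0.35) in the authors' deposited table, and G2/M genes 8, 2 and 19. In the interferon response list 9 of 39 rose and 2 fell, with Igtp at 0.74 in the authors' deposited table. Apoptosis and survival genes counted 7 that rose and 3 that fell of 26, among them Bcl2 at -0.54 in the authors' deposited table.

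Immunoglobulin and secretory genes went the other way in the knockdown. Of 13 tested immunoglobulin genes 8 fell and 0 rose, and the authors' deposited table gives -1.16 for Ighg3, -0.65 for Igha, -0.56 for Jchain and -0.18 for Ighm; constant regions are related in sequence, so their separate values are uncertain. The list median of -0.19 lay outside the range of matched random lists, and inside it once the trend of fold change on TPM was removed (-0.0658), and the Ighm value then went to -0.0003. In the plasma cell programme, whose median of -0.15 lay inside the range of matched random lists and outside it once that trend was removed (-0.11), 11 of 25 fell and 1 rose, with Sdf2l1 at -0.77 and Xbp1, a transcription factor of the secretory programme, at -0.67 in the authors' deposited table. Myc fell by 0.42 in the authors' deposited table, whereas Pvt1, next to Myc on chromosome 15, did not pass (0.03). Of 30 glycolysis and hypoxia genes 14 fell and 2 rose, with Bnip3l at -0.60 and Pdk1 at 0.55 in the authors' deposited table.

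In total 3177 of 12328 tested genes changed in the knockdown, 1625 up and 1552 down, and 115 of them by an absolute log2 fold change of at least 1. Of the 3177, 2551 also passed the authors' test for being unchanged, so most called changes were small. Among genes with a mean of at least 8 TPM over the groups compared, the largest falls after Mcm6 belonged to Zfp72 (-2.22), Bhlha15 (-2.10), Tmeff1 (-1.80), Pim2 (-1.72), Zfp689 (-1.68), Zkscan1 (-1.64) and Gnaz (-1.40) in the authors' deposited table. The largest rises among such genes were those of Cd300ld (2.99), Polm (2.59), Mylk2 (2.57), Tnfsf15 (2.46), Tnnt2 (1.48), Ica1l (1.48), Dusp1 (1.47) and Csf2rb2 (1.39) in the authors' deposited table. Genes that carry the 7-base sequence AACCCTA in their 3' UTR lay lower, at a median of -0.12 over 648 genes above 5 TPM, and Mcm6 carries it once in its own 3' UTR (1 site). Removing every gene with that sequence from the count left 2593 changed genes.

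The clone comparisons asked how C13 and C23 differed from the WT line. The 2 control groups, WT and shLacZ, were unlike in some lists and were not tested against each other. Tested glycolysis and hypoxia genes had a median of 168.4 TPM in WT and 71.1 TPM in shLacZ. Cholesterol synthesis genes had 26.3 and 58.5 TPM, and G1/S genes 61.1 and 84.7 TPM. Both clones share the WT samples, so a change in the clones cannot be told from a state of those samples. In C13 cholesterol synthesis genes rose, the direction opposite to that in the knockdown: 19 of 23 rose and 0 fell, with a list median of 0.80. Hsd17b7 (2.34), Insig1 (2.02) and Msmo1 (1.78) were among them in the authors' deposited table. G1/S genes counted 19 that rose and 0 that fell of 22, with log2 fold changes in the authors' deposited table of 1.58 for Ccne2, 1.31 for Rrm2, a subunit of ribonucleotide reductase, and 0.94 for Uhrf1. Replication fork genes followed, with 16 that rose and 1 that fell of 32 and Fen1 at 1.09 in the authors' deposited table, as did DNA damage genes, with 17 and 5 of 40, and licensing genes, with 11 and 4 of 27. Of the 6 helicase subunits, the authors' deposited table gives rises of Mcm2 (0.36), Mcm7 (0.34), Mcm5 (0.30) and Mcm3 (0.14), a fall of Mcm4 (-0.26) and no call for Mcm6 (0.05).

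Stress and hypoxia genes fell in C13. Of 27 integrated stress response genes 20 fell and 1 rose, with Nupr1 at -2.67, Trib3 at -1.96 and Cth at -1.25 in the authors' deposited table. Glycolysis and hypoxia genes counted 22 that fell and 1 that rose of 30, with Ndrg1 at -1.37 and Vegfa, the vascular growth factor, at -1.34 in the authors' deposited table. B-cell identity genes moved both ways, 17 up and 9 down of 38, with Cd72 at 1.27 and Blk at -0.79 in the authors' deposited table. Of 48 histone genes 11 rose and 4 fell, of 29 G2/M genes 12 rose and 1 fell, and of 25 plasma cell genes 9 rose and 5 fell. In the p53 target list 7 of 30 rose and 9 fell; Cdkn1a, which encodes the cell cycle inhibitor p21, stood at -2.11 and Zmat3 at 1.10 in the authors' deposited table.

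Several genes were nearly lost from C13. The log2 fold changes of Bbx (-9.19), Gpm6a (-8.71), Vill (-7.64), Zmat1 (-7.07) and Tctex1d2 (-5.44) in the authors' deposited table started from 31.2, 54.7, 30.6, 32.6 and 25.7 TPM in WT. Some lambda light chain segments did the same, with Iglc1 at -6.25 from 1117 TPM, Iglj1 at -6.24 and Iglj3 at -5.52 in the authors' deposited table, whereas Iglc2 stood at -0.84 from 824.8 TPM; these segments share sequence, so reads may be split among them. Among genes with a mean of at least 8 TPM over the groups compared, the largest rises were those of Cask (3.88), Crisp3 (3.72), Grap2 (3.66), Gcnt1 (3.61), Pmel (3.43), Gpr34 (3.26), Actr3b (3.26) and Myoz1 (2.97) in the authors' deposited table. Igha (-0.06, p = 0.2302) did not pass in the authors' deposited table, while Ighm (-0.36), Pvt1 (-0.24) and Myc (-0.12, p = 0.0478) fell. With the trend on TPM removed the Ighm value was -0.13, that of Myc -0.0155 and that of Mcm3 0.21, and, of the genes that did not pass, that of Igha 0.11 and that of Mcm6 0.11. In total 4315 of 12648 tested genes changed in C13, 2104 up and 2211 down, 743 of them by an absolute log2 fold change of at least 1. Of the 4315, 2668 also passed the test for being unchanged.

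In C23 glycolysis and hypoxia genes fell by the widest margin of any list in the 3 comparisons. Their median in the shared WT samples was 168.4 TPM, against 71.1 TPM in shLacZ. Of 30 tested members 28 fell and 0 rose, at a median of -1.22, with Slc16a3, the lactate exporter, at -4.06, Ndrg1 at -3.85, Bnip3 at -3.76 and Ankrd37 at -3.60 in the authors' deposited table. NF-kB targets counted 16 that fell and 0 that rose of 30, among them Ier3 (-2.34) and Nfkbiz (-1.36) in the authors' deposited table. In the IL-4 and TGF-beta list 16 of 33 fell and 5 rose, with Socs3 at -2.02, Ccl22 at -1.77 and Id2 at -1.72 in the authors' deposited table. B-cell identity genes counted 23 that fell and 7 that rose of 38, with Spi1 at -0.98 and Cd74 at -0.85 in the authors' deposited table. Their median of -0.26 lay inside the range of matched random lists once the trend on TPM was removed (-0.0771).

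More replication genes rose than fell in C23, as was also the case in C13, and many did not pass. Of 22 G1/S genes 15 rose and 1 fell, and Ccne2 stood at 1.22 and Rrm2 at 1.17 in the authors' deposited table. Licensing genes counted 15 that rose and 1 that fell of 27, led by Cdc6 (1.19) and Gins1 (0.84) in the authors' deposited table, replication fork genes 17 and 4 of 32, and DNA damage genes 21 and 4 of 40. G2/M genes did not follow: 1 of 29 rose and 16 fell, with Cdk1 and Hmmr both at -0.56 in the authors' deposited table, although the list median of -0.18 lay inside the range of matched random lists, and outside it once the trend was removed (-0.11). Of 73 ribosomal protein genes 39 fell and 0 rose, at a median of -0.42 outside the matched range. Mcm7 (0.54), Mcm2 (0.47) and Mcm5 (0.35) rose in the authors' deposited table, while Mcm3 (0.09), Mcm4 (0.00) and Mcm6 (-0.11) did not pass; with the trend on TPM removed these 3 values were 0.25, 0.20 and 0.0096.

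In total 4313 of 12648 tested genes changed in C23, 2015 up and 2298 down, 369 of them by an absolute log2 fold change of at least 1. Of the 4313, 3036 also passed the test for being unchanged. Among genes with a mean of at least 8 TPM over the groups compared, the largest falls beyond the hypoxia genes were those of Rgs11 (-6.00), Gp6 (-4.42), Cd7 (-3.73) and Nr4a1 (-3.19), and the largest rises those of Pmel (4.30), Lrriq1 (3.97), Pfn2 (2.55), Csf1r (2.52), Myoz1 (2.36), Maged1 (2.12), Klrg1 (2.12) and Cox6a2 (1.95) in the authors' deposited table. Ighm (-0.92), Myc (-0.57), Igha (-0.42) and Pvt1 (-0.24) fell in the authors' deposited table. Abundant genes as a class lay lower in C23: genes over 800 TPM in WT had a median log2 fold change of -0.64, and 56 of the 58 fell. Removing the trend of fold change on TPM brought Igha to 0.053, Ighm to -0.26, Cd74 to -0.26 and Myc to -0.28, so the sign of the Igha value and the size of the others depend on that trend.

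**Figure D2:**
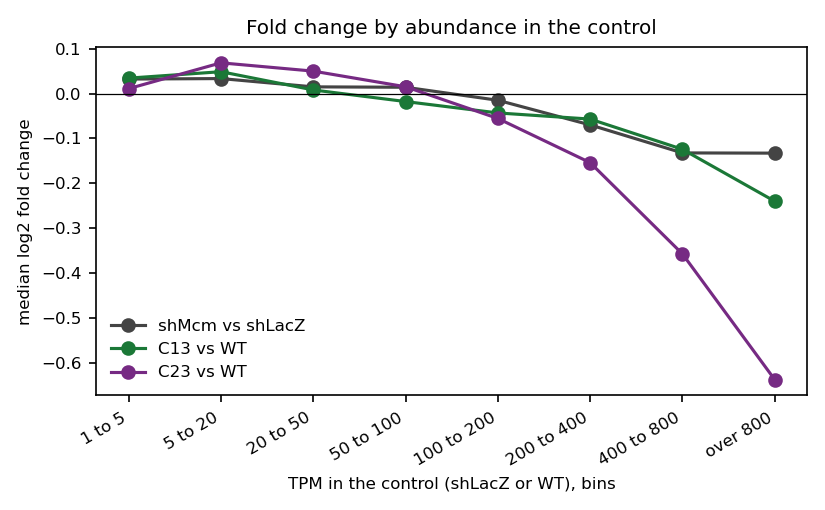
Points give the median log2 fold change of the genes in each bin of TPM in the control, for each of the 3 comparisons. From the bin of 20 to 50 TPM to that over 800 TPM the median went from 0.05 to -0.64 in C23, from 0.01 to -0.24 in C13 and from 0.02 to -0.13 in shMcm.

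**Figure D3:**
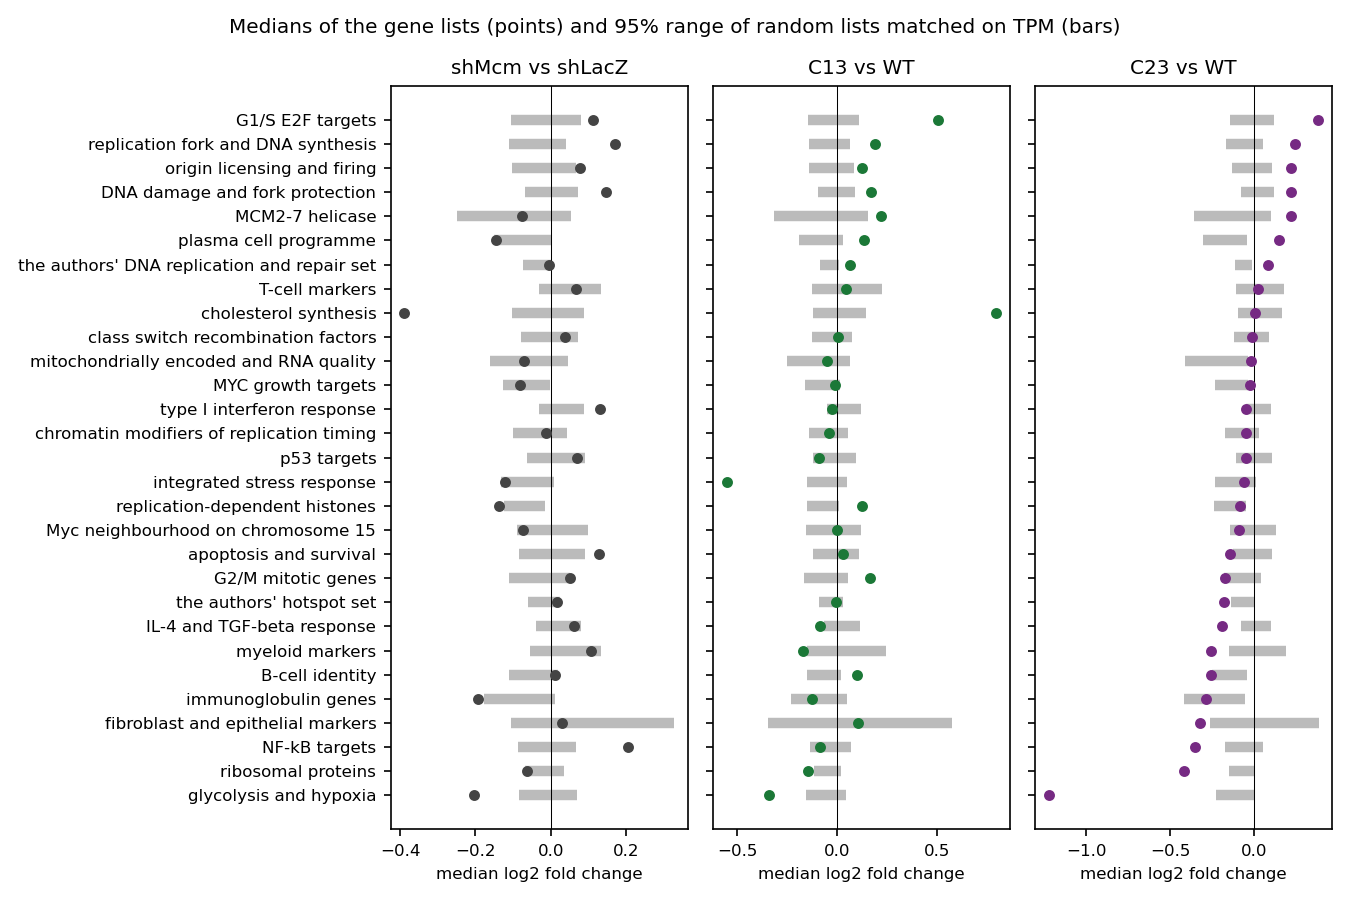
Points give the median log2 fold change of the gene lists in the 3 comparisons, and grey bars the 95% range of 10000 random lists of the same size matched on TPM; the horizontal scales differ between panels. Cholesterol synthesis stood at -0.39 in shMcm and 0.80 in C13, and glycolysis and hypoxia at -1.22 in C23.

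The authors marked 2 sets of genes in the same file, and whether these were chosen on these samples is not stated, so their direction is not independent evidence. In their DNA replication and repair set 24 of 130 tested genes rose and 21 fell in shMcm, against 39 and 13 in C13 and 45 and 21 in C23. In their hotspot set 17 of 78 rose and 18 fell in shMcm, 11 and 26 of 79 in C13, and 7 and 40 of 79 in C23, where Junb stood at -1.47 and Maff at -1.44 in the authors' deposited table.

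The clones changed many of the same genes against their shared WT samples. Of the 12648 genes tested in both, 2496 passed in both, 2285 with the same sign and 211 with opposite signs, where independent lists of these sizes would share 736.9 with the same sign. Simulated unchanged groups against shared controls gave at most 0 such genes. Adjusted p-values of groups drawn without change nearly always give that result, so it does not measure what the shared controls add. That simulation leaves out real effects and the value for independent lists leaves out the shared controls, so part of the excess over the latter may come from those controls. The log2 fold changes of C13 and C23 correlated across genes with Pearson's r = 0.559 and Spearman's rho = 0.602, against a mean r of 0.4998 in the simulation, and genes are not independent replicates. Their covariance was 0.141, against 0.0070 in the simulation, whose spread was read back from the authors' p-values. The authors' moderated fold changes may make that spread too small, and a median per TPM class leaves out the genes of widest spread. The simulated covariance may therefore be too low, so the comparison cannot show how far the observed value exceeds an effect of the shared controls.

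Pmel, a melanosome protein, rose in both clones, at 3.43 and 4.30 in C13 and C23 in the authors' deposited table. Ddx25 (3.94 and 3.06), Gcnt1 (3.61 and 2.66), Csf1r (2.57 and 2.52), Samd4 (2.79 and 2.39) and Myoz1 (2.97 and 2.36) also rose in both, and Tspan13 (-3.35 and -2.89) and Osgin1 (-2.28 and -2.61) fell in both in the authors' deposited table. Opposite signs were seen for Cox6a2 (-1.50 and 1.95), Ccl22 (1.22 and -1.77), Tjp3 (-3.74 and 1.10), Tlr4 (-2.11 and 1.09) and Ms4a6c (1.10 and -1.08) in the authors' deposited table.

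The difference between the clones, C23 minus C13, was not tested, since the file holds no such comparison. Among genes that changed in either clone and had a mean of at least 8 TPM over WT and both clones, it was largest upward for Bbx (8.61), Gpm6a (8.07), Unc5b (7.60), Vill (7.40) and Zmat1 (6.66), which were nearly lost from C13, and largest downward for Rgs11 (-5.01), Crisp3 (-4.02), Slc16a3 (-3.80), Gp6 (-3.45) and Ccr1 (-3.40). Among the list medians of this difference outside the 95% range of matched random lists were those of cholesterol synthesis genes (-0.88), glycolysis and hypoxia genes (-0.84), B-cell identity genes (-0.48) and integrated stress response genes (0.43).

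Knockdown and clones share no samples, and across all genes their fold changes were nearly uncorrelated. Some lists did go the same way in the knockdown and both clones. More G1/S, replication fork, licensing and DNA damage genes rose than fell, and more glycolysis and hypoxia genes fell than rose. Cholesterol synthesis genes and NF-kB targets did not share a direction. Called genes overlapped beyond independent lists in every pairing of signs. With C23, 432 fell in both against 288.7, and 450 rose in shMcm and fell in C23 against 302.2. The log2 fold change in shMcm correlated with the mean of the clones at Pearson's r = -0.0089 and Spearman's rho = 0.0043 over 12328 genes, and 50.9% of genes had the same sign. With C13 alone r was 0.0237, and with C23 alone -0.0515.

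Chromosome medians were compared with those of all other genes by an exact permutation test of chromosome labels, two-sided and adjusted over 20 chromosomes, in which genes are treated as independent although neighbours are not. Genes of chromosome 16 had a median of -0.25 in C13 (adjusted p = 6.53e-48, 412 genes) and -0.06 in C23 (adjusted p = 2.53e-05), where the median was -0.12 with genes of at least 8 TPM. Chromosome 8 genes had medians of 0.06 in C13 (adjusted p = 3.27e-06) and 0.05 in C23 (adjusted p = 8.25e-04), and in C13 chromosome 10 genes a median of -0.08 (adjusted p = 4.70e-12) and chromosome 13 genes one of 0.04 (adjusted p = 0.0471, 493 genes). Chromosome 13 no longer passed in C13 with genes of at least 8 TPM (adjusted p = 0.0557) or with the trend on TPM removed (adjusted p = 0.0736), and with genes of at least 8 TPM the chromosome 8 median in C13 was 0.04. Other chromosomes passed in the clones under an alternative alone: with genes of at least 8 TPM chromosome 10 in C23 (-0.05, adjusted p = 0.0093) and chromosome 11 in C13 (0.01, adjusted p = 0.0183), and with the trend removed chromosome 17 in C13 (-0.03, adjusted p = 0.0278). In shMcm chromosomes 1, 7 and 15 passed with medians of 0.03, -0.02 and -0.02. With genes of at least 8 TPM chromosome 7 alone passed there, at a median of -0.04, and with the trend removed chromosomes 1 and 7 did.

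Runs of neighbouring genes, in the gene order of GRCm38, an assembly other than the mm9 build the authors used, shifted together in C13 on chromosomes 8, 10 and 16 and in C23 on chromosome 8, and 0 runs were found in shMcm. At the start of chromosome 8, the 90 genes from Mcoln1 to Leprotl1 had a median of 0.77 in C13 and 0.47 in C23, against 0.02 in shMcm. On chromosome 10, the 150 genes from Sar1a to Matk had a median of -0.44 in C13 and -0.17 in C23. On chromosome 16, the 45 genes from Snx29 to Ess2 had a median of -0.34 in C13 and -0.09 in C23. The 75 genes from Gm4827 to Chaf1b had -0.47 and -0.21. The lost gene Bbx and the lambda light chain genes lie on chromosome 16, and Mcm4, which fell in C13, lies there too. Gpm6a, also nearly lost from C13, lies on chromosome 8. The near-total losses are far larger than the run medians.

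**Figure D4:**
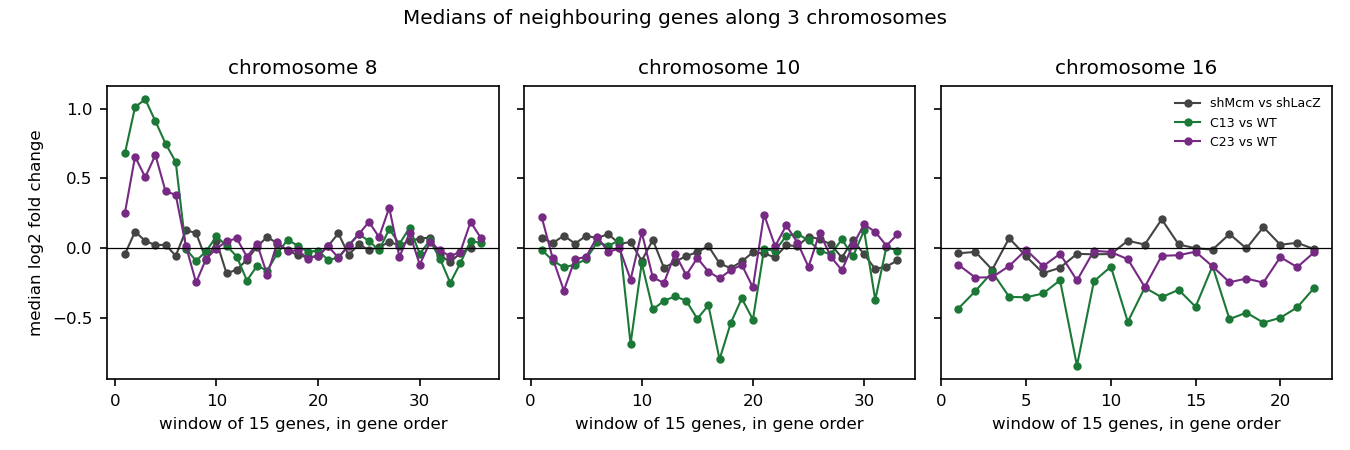
Points give the median log2 fold change of consecutive windows of 15 genes along chromosomes 8, 10 and 16, in the gene order of GRCm38, for the 3 comparisons. The run from Mcoln1 to Leprotl1 at the start of chromosome 8 stood at a median of 0.77 in C13 and 0.47 in C23.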

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

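The tests of zinc finger genes alone and of both explanations for abundant genes were chosen after their results, or values from which these could be inferred, had been seen, and the searches that found the patterns were chosen after the data were seen. The difference C23 minus C13, taken gene by gene, had a median of 0.21 over 412 genes of chromosome 16, against -0.0090 over other genes. The exact permutation of chromosome labels among genes gave an adjusted p of 3.50e-38, which compares genes and not replicates.

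Runs of neighbouring genes shifted together in C13, and in part in C23, on chromosomes 8, 10 and 16. An abundance trend is argued against, since at least 0.907 of each segment's median in C13 remained once the trend was removed. A gain or loss of chromosome segments was tested on genes under 5 TPM within the segments, which had no part in finding them: 44 of 75 (58.7%, exact 95% interval 46.7 to 69.9) shared their segment's sign, against 44.1% outside. That excess rests on chromosome 8, where 21 of 22 did. Over the others the count was 23 of 53 (43.4%, exact 95% interval 29.8 to 57.7) against 36.5%, which decides nothing. By segment it was 17 of 35 on chromosome 10, and on chromosome 16 it was 3 of 6 and 3 of 12 in the runs starting at Snx29 and Gm4827. A gain on chromosome 8 is thus a candidate explanation, and on chromosomes 10 and 16 a loss stays open. Joint regulation of neighbours, which predicts the same, was not told from either, since DNA copy number was not analysed here. Both clones were set against the same WT samples, and the chromosome 8 run was up in both. A gain or loss in a clone therefore cannot be told from the opposite state of the WT samples.

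Genes whose transcripts carry AACCCTA fell in shMcm, with the lowest rank z of 16204 sequences in 3' UTRs (-14.2) and of 16383 in coding sequences (-11.4). Composition of the 3' UTR does not account for the fall, since the coefficient of the site was -0.197 (95% interval -0.224 to -0.169) beside length, GC share and TPM, though A-rich coding sequences reached a z of 13.1 in the other direction. Genes named Zfp or Zkscan, the zinc finger genes of this test, do not alone account for it either. The 718 other tested genes of any TPM with the site in the 3' UTR had a median of -0.0702 (95% interval -0.0964 to -0.0550). Zinc finger genes under other names were not set apart from these 718. A family response of zinc finger genes in addition cannot be told apart, because those without the site had a median of -0.0154, at the lower limit of matched random lists (-0.0156), with a 95% interval of -0.0647 to 0.0153; the bound alone, set beforehand, would have excluded it, and the interval was brought in after the value was seen. Seed pairing of the short hairpin RNA may explain the pattern: the median went from 0.01 with 0 sites to -0.11 with 1 and -0.30 with 2 or more. The sequence was found through the fall of its carriers in these same fold changes, so the step from 0 to 1 site is not independent support. That search scored the presence of a sequence and not its number of sites. These steps were taken over zinc finger and other genes together, and the hairpin's sequence was not used here.

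Abundant genes fell together in C23. A few genes taking a changed share of the reads would move all genes alike, and is argued against by a median 0.45 lower above 400 TPM than at 20 to 50 TPM (difference -0.45, 95% interval -0.50 to -0.42). An upper limit of measured abundance that differs between libraries would lower unlike RNA classes alike. Above 400 TPM the medians of 65 other RNAs and 263 protein-coding genes differed by -0.0644 (95% interval -0.17 to 0.04). The other RNAs include small RNAs but also immunoglobulin segments such as Ighm and Igkc, which are parts of protein-coding transcripts. The classes thus overlap in origin, and near-equal medians cannot tell such a limit from a real fall. The highest value, that of Ighm, was 1574 TPM in WT and 1091 TPM in shLacZ. The 10 highest genes held 1.44% and 1.04% of all TPM. So flat a top is what a limit would give, but no TPM of C23 is given to compare. Under such a limit the fold changes of the most abundant genes would not measure their RNA. A real change of the most abundant RNAs in the clone was not tested and stays open.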

How the results depend on the processing

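All alternatives except the filter at 1 TPM and the single clones were chosen after the data were seen. Requiring an absolute log2 fold change of at least 1 left 115 changed genes in shMcm, 743 in C13, 369 in C23 and 184 with the same sign in both clones, by construction. The filter at 1 TPM, a p under 0.01, and removal of chromosomes 8, 10 and 16 or of genes with AACCCTA kept each count within 1.5 times. The share of changed genes that fell in C23 went from 53.3% to 49.9% once the abundance trend was removed; the cause of the trend was not settled. The correlation of shMcm with the clones stayed near 0: -0.0089 for their mean, 0.0237 for C13, -0.0515 for C23, -0.0321 at 8 TPM or more and -0.0297 without the trend; the cause was not tested. With genes of at least 8 TPM 1 chromosome passed in shMcm in place of 3, with fewer genes tested. Over all called genes, removing the trend turned the sign of 146 in C23, 15 in shMcm and 7 in C13. Among list medians outside the matched range it turned those of MYC growth targets (0.0312) and RNA quality genes (0.0602) in C23. Among the named genes that were called it turned Igha (0.0531), Mthfd2 (0.0312) and Hspa5 (0.0494) in C23, and H1f1 (0.0228) and Rpl4 (0.0024) in shMcm. Of the other named-gene values 279 moved by under 0.1 and 71 by more. Both list medians that turned sign and 4 others came inside the matched range while 5 left it, and some medians inside that range also changed sign. Other count tools, normalizations, count filters, prior counts, pseudocounts, fits of all libraries, set tests and leaving out replicates were not run, since they need values per library, and for the same reason other splits of the samples were not counted. Adjustment over a list alone was not made, since the p-values appear to be adjusted already. No paired analysis was possible because the columns carry no replicate numbers.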

Other observations

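Further list results not given above were these. In shMcm 12 of 27 integrated stress response genes fell and 4 rose, and the median of 38 B-cell identity genes (0.01; 6 rose, 12 fell) lay inside the matched range. Of 47 histone genes 5 fell and 0 rose in shMcm, at a median of -0.14 outside the matched range and of -0.0459 inside it with the trend on TPM removed, and of 73 ribosomal protein genes 5 fell and 0 rose. In C13 16 ribosomal protein genes fell and 1 rose, at a median of -0.15 outside the matched range, and of -0.0921, still outside, with that trend removed. The IL-4 and TGF-beta list counted 6 that rose and 7 that fell of 32 in shMcm, and 9 and 13 of 33 in C13, where the median of -0.0869 lay outside the matched range, and inside it with the trend removed (-0.0672), and Fcer2a, the low-affinity IgE receptor, passed as higher and was listed at 0 TPM in WT in the authors' deposited table. NF-kB targets counted 5 that rose and 10 that fell of 30 in C13. Plasma cell genes counted 12 that rose and 6 that fell of 25 in C23, at a median of 0.15 outside the matched range (0.28 with the trend removed). Apoptosis and survival genes counted 2 that rose and 6 that fell of 27 in C13, and 4 and 13 in C23, where the median of -0.14 lay outside the matched range. Of 48 histone genes 5 rose and 16 fell in C23. Interferon response genes counted 4 that rose and 9 that fell of 41 in C13, and 7 and 8 in C23, and immunoglobulin genes 4 and 7 of 14 in C13, and 1 and 7 in C23. Cholesterol synthesis genes counted 4 each way of 23 in C23, and integrated stress response genes 4 that rose and 8 that fell of 27. Class switch recombination factors counted 7, 9 and 8 that rose and 5, 7 and 6 that fell of 35 in shMcm, C13 and C23, and Lig4 stood at 1.14 in C13 and 1.03 in C23 in the authors' deposited table. MYC growth targets counted 4, 9 and 7 that rose and 10, 10 and 15 that fell of 41, and p53 targets 8 that rose and 2 that fell of 30 in shMcm, and 5 and 10 in C23. Genes around Myc counted 2, 3 and 2 that rose and 4, 6 and 6 that fell of 18.

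Markers of other cell types were in part abundant: Tyrobp stood at 304.8 TPM, Lck at 131.6 and Fcgr3 at 81.2 in WT in the authors' deposited table. Of 11 tested myeloid markers 4 rose in shMcm, among them Adgre1 (2.23) and Itgam (1.59) in the authors' deposited table. In C13 2 rose and 4 fell, at a median of -0.17 outside the matched range, and in C23 1 rose and 4 fell, at a median of -0.26 also outside it, with Csf1r at 2.52 and Itgam at -3.27 in the authors' deposited table. T-cell markers counted 2 that rose and 0 that fell of 11 in shMcm, 1 and 3 in C13, and 0 and 1 in C23. Chromatin modifiers linked to replication timing counted 7 that rose and 7 that fell of 34 in shMcm, 5 and 8 in C13, and 5 and 7 in C23. The list of mitochondrially encoded and RNA quality genes counted 1, 2 and 4 that rose and 3, 5 and 6 that fell of 12 in shMcm, C13 and C23. Its tested members include noncoding RNAs encoded in the nucleus, such as Malat1, Neat1, Rmrp and Rpph1. The counts therefore do not describe mitochondrially encoded genes. Of 3 tested fibroblast and epithelial markers 1 rose in shMcm, 1 in C13 and 0 in C23, and 0 fell; the C23 median of -0.32 lay outside the matched range, although 0 of the 3 passed. Erythroid markers had too few tested members.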
